A study of Homo sapiens with 2 samples.

How the data were processed

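RNA was measured in 2 libraries of MCF-7, an estrogen receptor positive breast cancer cell line. The control group carried a GFP vector, per the labels, called the control vector here. The other group carried a retroviral construct for EPIC1, a long noncoding RNA. Each group had 1 library. Per the labels, virus was collected after 48 h, the cells were infected for 24 h, and stable cells were selected with puromycin. Total RNA was depleted of ribosomal RNA with a KAPA kit, per the labels' protocols.

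The authors deposited a gene table and a repeat table. The gene table holds log2 values, and the deposited numbers were read as log2(FPKM + 1) because the values turned back with an offset of 1 fell on steps of whole reads. The deposited repeat table holds log2(count + 1), since all 240 values turned back to within 1e-06 of a whole count. The authors' log2 fold column lies within 1e-06 of the plain difference of its columns in all 120 families, with no scaling for depth. The submitters' processing notes name Bowtie2, STAR, RSEM and the build hg38, with no versions. The deposited repeat table is labelled as a RepEnrich quantification. Which of the named tools made the gene table, the annotation release and the strand setting are not given in the sources used here.

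Of 60468 gene rows, 19284 were above 0 in either library. Some names occur on several rows, with 2471 rows sharing a name, and the row with the higher mean was kept, which left 19225 names above 0. Values were turned back to FPKM, and differences were taken as log2(FPKM + 1) of the EPIC1 library minus that of the control library, which understates the change of low genes. Genes with a mean of at least 1 FPKM entered the counts, 15959 in all, and 11295 of these matched a name in GENCODE release 29. That release gave transcript lengths, gene types and positions on hg38.

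Depth was recovered from genes with 1 annotated transcript of at least 600 nt. For values of up to 10 reads, the FPKM multiplied by the transcript length less a fixed trim fell within 0.05 of a whole multiple of 1 read for 93.8% of 985 genes in the control library and 92.7% of 953 in the EPIC1 library, against 10% by chance. The trim was 195 and 190 nt. The step implies about 672000 and 658000 fragments behind the gene values, a depth ratio of 0.979. The number of fragments sequenced is not known from these values. Reads of genes with several transcripts are known only as upper limits, from the longest transcript, and the true number can be far lower. Reads were given for genes whose longest transcript less the trim was at least 100 nt. Intervals are exact conditional binomial (Clopper-Pearson) 95% intervals and cover counting error only. The gene values are rounded FPKM and not counts, so no count model was run.

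With 1 library per group no test of the condition was possible and no p-value is given. Genes at least 2-fold apart were counted in each direction. Observed numbers were set beside 100 binomial splits of the same reads. For each of 29 gene lists, the median difference of members above the floor was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Its percentile describes these 2 libraries. Repeat families with at least 10 counts over both libraries were compared by log2 ratio with a pseudocount of 0.5.

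The genes named were fixed by rule before the data were examined: EPIC1, the 12 largest differences in each direction among genes with a mean of at least 1 FPKM (ribosomal and small RNA classes left out), up to 4 members of each list with the largest absolute difference, and the 5 highest and 5 lowest repeat families. The text gives most but not all of them. Other features were chosen after their values were seen, as stated where they appear. Alternatives tried were pseudocounts of 0.1 and 5 FPKM, no floor and a floor of 5 FPKM, rescaling to a common sum, median centring, a trimmed mean of log ratios, leaving out small RNA, ribosomal and mitochondrial genes, unmatched random lists, and for repeats other scalings, weights, minimums and pseudocounts. Others, restricting genes by reads or by overlap with an exon on the opposite strand, were added after the data were seen.

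The computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. They were tested on simulated data made from 13879 genes, in which 99.5% of 200 genes changed 4-fold came out at least 2-fold apart, and 0% of 1835 unchanged genes of at least 50 reads did.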

Results

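The comparison asks how a higher level of EPIC1, a long noncoding RNA from chromosome 22, alters the transcripts and the endogenous retrovirus families of MCF-7 breast cancer cells. Each group had 1 library, so no difference below has a replicate check. The gene values rest on about 672000 fragments for the control vector and 658000 for EPIC1 overexpression, which need not be all that were sequenced. The control library had 16587 rows above 0 and the EPIC1 library 16524. Among 1177 genes with 1 transcript and a mean of at least 1 FPKM, the median was 11 reads over both libraries, and 48.8% had 10 reads or fewer.

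No row of the gene table carries the name EPIC1, so the overexpressed transcript could not be checked by name. GENCODE release 29 places the gene, as AL117329.1, on the plus strand of chromosome 22 from 47631674 to 47855600 (hg38). A row with an older clone name, RP11-191L9.4, was listed at 0 in the control library and at 30.2 FPKM in the EPIC1 library, a log2 difference of 4.96. Its neighbour in name, RP11-191L9.5, stood at 16.3 and 27.6 FPKM, a difference of 0.72. These rows were chosen after their values were seen, and the pairing of either with EPIC1 is not established by the reference used here. The size of the first difference depends on the pseudocount, at 8.24 with 0.1 FPKM and 2.81 with 5 FPKM.

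Several rows at the head of the table overlap an abundant gene on the opposite strand. The row of KRT8, a keratin of simple epithelia, stood at 5599 FPKM in the control library, while its partner keratin KRT18, which overlaps it on the other strand, stood at 158. The ferritin heavy chain FTH1 was at 92.4 and BEST1, a chloride channel gene overlapping it, at 2485. PPIB, a peptidyl-prolyl isomerase of the endoplasmic reticulum, was at 23.5 and the overlapping SNX22, a sorting nexin, at 1084. Of the 100 highest rows in the reference, 62 overlap an exon on the opposite strand, against 4983 of 11195 other rows (44.5%). With mitochondrial rows, small RNA and genes under 400 nt left out, the number was 74, against 4933 of 10825 (45.6%). These pairs were chosen after their values were seen, and the strand setting is not given in the sources used here. Which strand the rows hold is therefore open for every gene named, with or without such an overlap.

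Of 15959 genes above the floor, 2964 were at least 2-fold higher and 3050 at least 2-fold lower in the EPIC1 library, 37.7% together. The 12 genes with the largest positive differences were all listed at 0 in the control library. AC097382.1, a noncoding transcript, led with 31628 FPKM in the EPIC1 library, followed by GNAS-AS1_5, a segment of the antisense transcript of the imprinted GNAS gene, at 748 FPKM. HOTAIR_5, a segment of the HOX antisense transcript, was at 304 FPKM. Differences in this group ran from 7.90 to 14.95 on the log2 scale. The 12 largest negative differences ran from −12.42 to −6.77, and 11 of these genes were listed at 0 in the EPIC1 library. AP003041.1, a processed pseudogene, stood at 5469 FPKM (3620 reads) and 0. RMRP, the RNA of a mitochondrial RNA processing ribonuclease, stood at 568 and 0.159 FPKM. Its longest transcript, of 268 nt, is too short for a read number here. SHBG, the carrier of sex hormones, was at 314 FPKM (at most 251 reads) in the control library. ZNF525, a zinc finger gene, was at 272 there, on at most 1079 reads and on 37 if the shortest transcript was counted. Pseudogenes and gene segments can share reads with near-identical copies, so values of 0 there are uncertain.

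**Figure D1:**
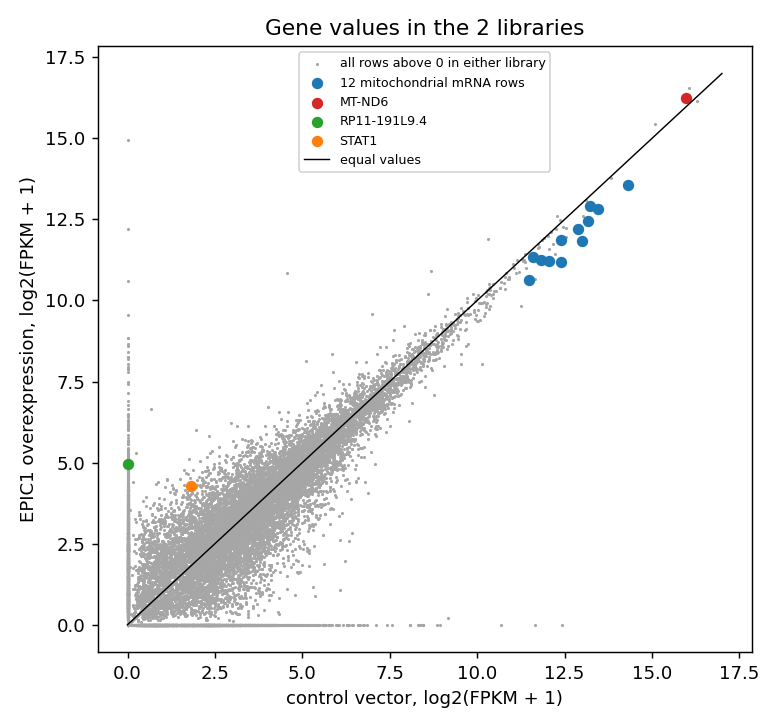
Each point is a gene row above 0 in either library, with log2(FPKM + 1) of the control library on the horizontal axis and of the EPIC1 library on the vertical axis, beside a line of equal values. The 12 coloured mitochondrial rows lie under that line and MT-ND6 above it, and RP11-191L9.4 lies at 0 on the control axis.

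Binomial splits of the same reads set a scale for these counts. Among the 1177 genes with 1 transcript, 348 were at least 2-fold apart, against a mean of 303 and a range of 279 to 326 over 100 splits. Among 227 such genes with at least 50 reads, 11 were at least 2-fold apart, against a mean of 0.48 and a highest value of 3. Over the 11159 genes matched to the reference and long enough for a read number, 3976 were apart, against a mean of 1405 and a highest value of 1480, but their reads are upper limits, which make the splits too narrow. The total count falls to 274 higher and 286 lower when genes are limited to 3484 with at least 50 reads at the upper limit, and with a pseudocount of 5 FPKM it is 1364 higher and 1325 lower.

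The 29 gene lists were compared by their median difference, and under the alternatives 35 of 286 list medians had the other sign, over 17 of the lists. Genes of antigen presentation and interferon signalling went both ways. Among MHC class I antigen presentation genes, 5 of 14 above the floor were at least 2-fold higher, 2 lower and 7 between, with a median of 0.13 at percentile 77.5 of random lists. NLRC5, the transactivator of MHC class I genes, was listed at 0 in the control library and at 15.0 FPKM with EPIC1 (at most 65 reads), while B2M, the MHC class I light chain, was at 6.91 FPKM (at most 10 reads) and 0. IRF1, an interferon-induced transcription factor whose row overlaps an opposite-strand exon, stood at 6.49 and 0.613 FPKM. HLA-A and TAP1, a heavy chain and a peptide transporter, were listed at 0 in both libraries, as 7 of the 21 members were.

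Type I interferon-stimulated genes had 6 of 27 higher, 7 lower and 14 between, with a median of −0.06 at percentile 38.3. STAT1, the signal transducer of interferon receptors, was 7.38-fold higher by FPKM, at 2.497 and 18.4 (at most 7 and 50 reads), and MX1, an antiviral GTPase, was at 3.70 and 0. Nucleic acid sensing genes had 3 higher, 3 lower and 4 between (median −0.04, percentile 47.1). Over the 5 members with at least 50 reads at the upper limit, that median turned to 1.25. This lies at percentile 98.9, outside the central range of random lists, but the true reads can be far fewer. IRF3, which drives interferon transcription, stood at 6.67 and 22.1 FPKM, and ADAR, an RNA-editing deaminase, at 8.31 and 21.2. DHX58, among the 3 lower, was at 7.94 and 2.78 FPKM (at most 13 and 4 reads). TLR3, a sensor of double-stranded RNA, was listed at 0 in both. Among interferons, receptors and JAK-STAT genes, 1 of 5 was higher and 2 lower (median −0.45, percentile 24.7), with the kinase TYK2 at 20.2 and 6.66 FPKM, and the receptor IFNAR1 was listed at 0 in both. Chemokines and inflammatory cytokines had 0 higher and 1 lower of 5 (median −0.08, percentile 43.0), the lower being CXCL16 at 18.9 and 3.52 FPKM. The rows of STAT1, MX1, IRF3 and CXCL16 overlap an exon on the opposite strand.

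Chromatin regulators stayed mostly within 2-fold. Of 9 genes of PRC2 and its cofactors, the complex that methylates histone H3, 2 were higher and 0 lower (median 0.20, percentile 72.8). RBBP4, a histone-binding subunit whose row overlaps an opposite-strand exon, was at 8.86 and 22.1 FPKM, and EZH1, a catalytic subunit, was at 0 and 3.68 (at most 11 reads). Silencers of endogenous retroviruses had 2 of 20 higher, 1 lower and 17 between (median −0.08, percentile 36.7). DNMT1, the maintenance DNA methyltransferase, was 2.17-fold higher at 35.4 and 76.7 FPKM. It rests on at most 124 and 263 reads, and on 1 and 2 if the shortest transcript was counted. CBX5, a heterochromatin protein, was 1.87-fold lower at 45.1 and 24.1.

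Genes linked to MYC and the cell cycle showed no common direction. Of the EPIC1 and MYC-linked genes of earlier reports, 0 of 7 were higher and 1 lower (median −0.33, percentile 18.02). MAX, the binding partner of MYC, was 4.94-fold lower at 43.2 and 8.75 FPKM. It rests on at most 86 and 17 reads, and on 4 and 1 if the shortest transcript was counted. MYC itself stood at 25.7 and 13.5 (at most 37 and 19 reads). MYC targets had 4 of 27 higher and 4 lower (median −0.05, percentile 44.1, mean 0.12 of the other sign). FBL, the nucleolar methyltransferase fibrillarin, was at 22.8 and 1841 FPKM, an 80.7-fold difference that rests on at most 18 and 1465 reads and on 5 and 375 if the shortest transcript was counted. CAD, an enzyme of pyrimidine synthesis, was at 9.63 and 1.29. S phase genes had 3 of 27 higher and 5 lower (median 0.02, percentile 61.8, mean −0.14), with RRM2, a ribonucleotide reductase subunit, at 13.8 and 1.31 FPKM and CDC6, a replication licensing factor, at 8.47 and 0. G2 and M phase genes had 4 of 28 higher and 6 lower (median 0.00, percentile 50.3, mean −0.16), with CKAP2, a spindle-associated protein, at 6.29 FPKM and 0 and CENPA, the centromeric histone, at 0 and 5.99. Targets of p53 had 4 of 15 higher and 2 lower (median −0.15, percentile 34.7). The 2 lower were the cell death genes BAX, at 38.7 and 6.57 FPKM, and FAS, at 43.0 and 11.8. Among the 4 higher, TP53I3 was at 2.48 and 10.3 FPKM (at most 3 and 12 reads). The MAX, FAS and TP53I3 rows overlap an exon on the opposite strand.

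Estrogen response genes had 5 of 20 higher and 2 lower (median 0.15, percentile 84.4). With a floor of 5 FPKM their median was 0.55 at percentile 99.4. With at least 50 reads at the upper limit it was 0.34 at percentile 97.9. Both lie outside the central range, while without opposite-strand overlap the median was −0.04 at percentile 48.98. STC2, a secreted stanniocalcin, was 5.81-fold higher at 3.24 and 18.8 FPKM (at most 11 and 64 reads). FOXA1, a pioneer factor of the estrogen receptor, was 3.05-fold higher at 20.8 and 63.3 (at most 37 and 111 reads). CA12, a carbonic anhydrase, was 3.14-fold lower at 20.2 and 6.42 (at most 84 and 26 reads). Luminal epithelial markers had 3 of 18 higher and 3 lower (median −0.18, percentile 23.2). MUC1, a membrane mucin, was at 3.87 and 34.8 FPKM (at most 10 and 91 reads). CDH1, the adhesion molecule E-cadherin, was at 35.0 and 6.39, on at most 110 and 20 reads and on 2 and 0 if the shortest transcript was counted. Basal epithelial markers had 4 of 5 higher and 0 lower (median 1.47, percentile 96.7), among them ITGB4, a hemidesmosome integrin, at 17.97 and 51.5 FPKM and CD44, an adhesion receptor, at 0 and 6.02. Another 9 of its 17 members, including the keratins KRT5, KRT14 and KRT17 and the transcription factor TP63, were listed at 0 in both libraries. The list lay outside the central range against unmatched random lists (percentile 97.9), with a pseudocount of 5 FPKM (median 0.89) and with no floor (median 0.83). Mesenchymal and fibroblast markers had 0 of 7 higher and 3 lower (median −0.38, percentile 19.7), with ZEB1, a repressor of epithelial genes, at 18.2 and 5.53. Opposite-strand exon overlap applies to the rows of FOXA1, CDH1, CD44 and ZEB1.

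Markers of other cells gave few values. Immune cell markers had 1 of 4 higher and 0 lower (median −0.02, percentile 50.4, mean 0.92), the higher being NKG7, a granule protein of killer cells, at 0 and 16.7 FPKM (at most 7 reads). Packaging cell transcripts, included because the virus was made in another line, had 2 members above the floor (median −0.68, percentile 22.9), with NCAM1 at 10.04 and 2.97 FPKM and VIM at 11.2 and 12.2, both rows with an opposite-strand exon overlap.

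Hypoxia and glycolysis genes had 5 of 17 higher and 1 lower (median 0.36, percentile 95.7). The list lay outside the central range with a pseudocount of 5 FPKM (percentile 97.9) and without opposite-strand overlap (median 1.32 over 7 members, percentile 98.2). LDHA, a lactate dehydrogenase subunit, was 3.81-fold higher at 7.78 and 29.6 FPKM (at most 12 and 43 reads). CA9, a hypoxia-induced carbonic anhydrase, was at 0 and 9.85 FPKM (at most 9 reads). The mTORC1 and amino acid response list had 3 of 16 higher and 1 lower (median 0.27, percentile 84.1), with the amino acid transporter SLC7A5 at 16.1 and 37.5 FPKM and the stress factor ATF4 at 19.5 and 7.41. Unfolded protein response genes had 3 of 16 higher and 1 lower (median 0.10, percentile 73.7), with PDIA4, a disulfide isomerase, at 3.30 and 7.89. Heat shock genes had 0 of 11 higher and 3 lower (median −0.15, percentile 31.9), with the cochaperone DNAJB1 at 24.98 and 10.9. Cholesterol biosynthesis genes had 6 of 18 higher and 5 lower (median 0.16, percentile 78.1). MVD, mevalonate decarboxylase, was at 35.8 and 2.53 FPKM, on at most 52 and 4 reads and on 1 and 0 if the shortest transcript was counted. FDFT1, squalene synthase, was at 3.40 and 21.3 (at most 6 and 35 reads). Immediate early genes had 2 of 12 higher and 2 lower (median 0.34, percentile 82.5), with the transcription factor KLF2 at 0 and 16.2. An opposite-strand exon overlaps the rows of CA9, SLC7A5, DNAJB1 and FDFT1.

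Ribosomal protein genes had 30 of 34 within 2-fold, 2 higher and 2 lower (median −0.11, percentile 31.2), and RPS15, of the small subunit, was 2.21-fold lower at 116 and 52.4 FPKM. Housekeeping genes had 13 of 14 within 2-fold and 1 lower (median −0.26, percentile 17.6). The lower gene was HPRT1, at 3.67 FPKM (at most 3 reads) and 0. PPIA, cyclophilin A, at 23.9 and 11.5 FPKM, was just within the bound, with a log2(FPKM + 1) difference of −0.99. Replication-dependent histones had 2 of 19 higher and 4 lower (median −0.16, percentile 26.2), with HIST1H4C at 67.4 and 18.4 (at most 11 and 3 reads). Neighbours of EPIC1 on 22q13 had 4 of 11 higher and 1 lower (median 0.48, percentile 89.3), led by GRAMD4, at 0 and 24.9 FPKM (at most 70 reads), which lies on chromosome 22 from 46576012 to 46679790 (hg38).

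**Figure D2:**
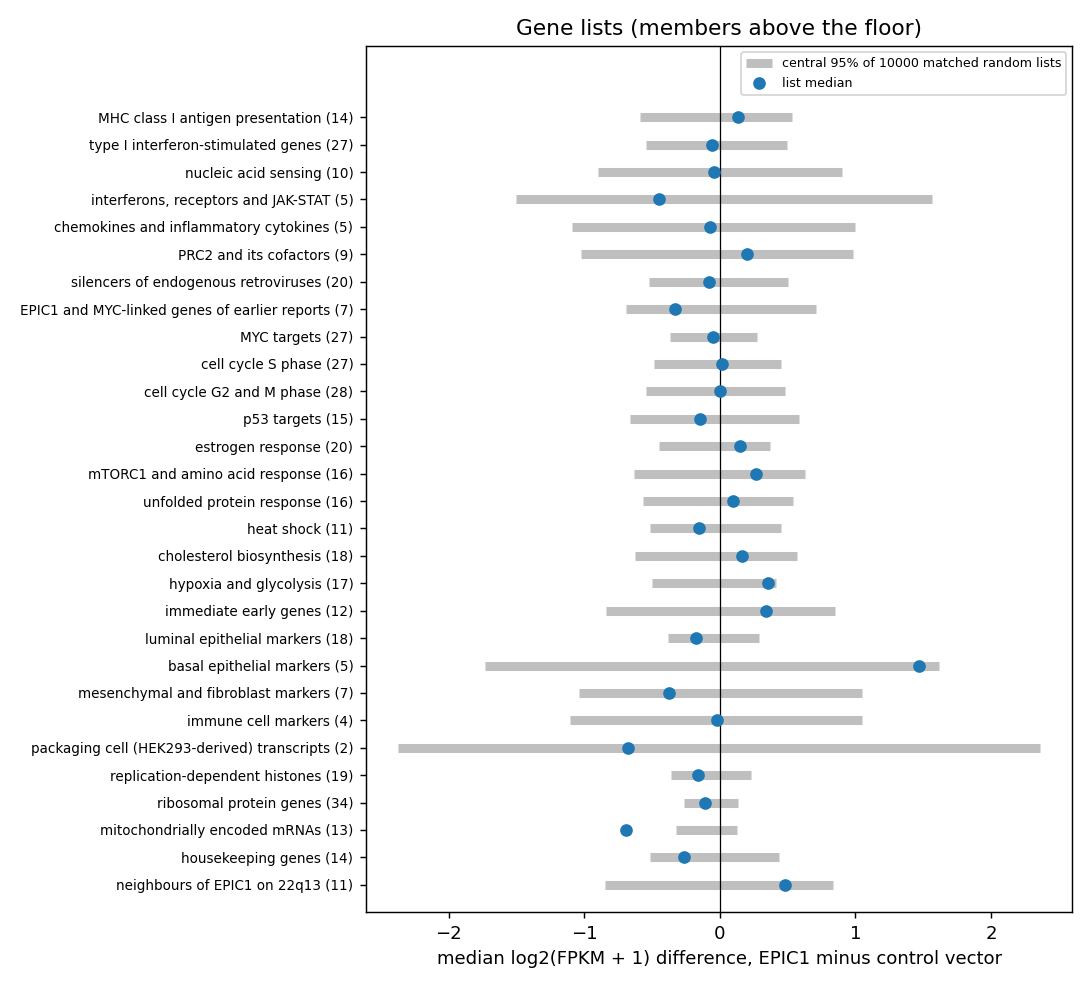
Points show the median log2(FPKM + 1) difference, EPIC1 minus control, of each gene list, with the number of members above the floor in brackets, and grey bars show the central 95% of 10000 matched random lists. The mitochondrially encoded mRNAs, at −0.69, are the 1 list of 29 outside its bar, where 1.45 would lie outside by chance.

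Mitochondrially encoded mRNAs, which code for subunits of the respiratory chain, were the list outside the central range as deposited. Which strand these rows measure is not settled. If reads were counted on the opposite strand, the rows other than MT-ND6 would not give the direction of their mRNAs. The MT-ND6 row would then cover only its own stretch of the other strand. The median difference of the 13 rows was −0.69, at percentile 0 of random lists, whose central range was −0.32 to 0.13. Against random lists not matched on expression it stood at percentile 2.36, close to the bound of 2.5. All rows but MT-ND6 were lower in the EPIC1 library, by 1.21-fold to 2.30-fold, and the median of those 12 was 6488 FPKM in the control library and 3689 in the EPIC1 library. MT-ND4, a subunit of complex I, stood at 8233 and 3679 FPKM (6546 and 2875 reads; interval of the log2 ratio −1.22 to −1.09), and MT-CO1, a subunit of cytochrome oxidase, at 4230 and 2357. MT-ND6, the complex I subunit encoded on the other strand, was at 64453 and 77545 FPKM, a difference of 0.27 (interval 0.26 to 0.32). Its row was 9.93 times the median of the others in the control library and 21.02 times in the EPIC1 library. The intervals cover counting error between these 2 libraries and not the spread between cultures.

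**Figure D3:**
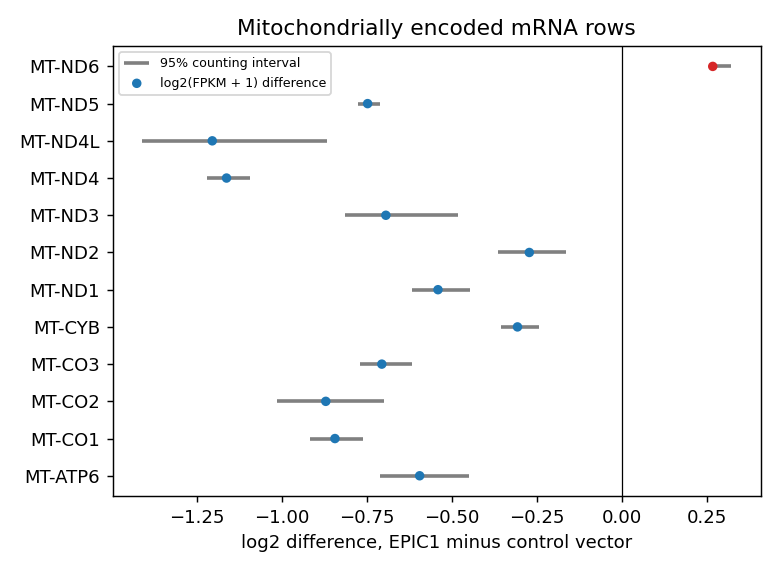
Points show the log2(FPKM + 1) difference, EPIC1 minus control, of the 12 mitochondrially encoded mRNA rows that have a counting interval, and bars show that 95% interval. MT-ND6, in red, lies at 0.27, and the others lie under 0.

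Endogenous retrovirus families, remnants of retroviruses counted by repeat family, differed little. Of 55 families with at least 10 counts, 19 were higher, 34 lower and 2 equal in the EPIC1 library, with a median log2 ratio of −0.06. Scaled to the table's total, 27 were higher and 28 lower, with a median of −0.01. Counts over all families were 58596 and 56607, a log2 ratio of −0.05 (95% counting interval −0.07 to −0.03). The 22 families past 1000 counts ranged from −0.16 to 0.14. LTR13A, a long terminal repeat family, was the 1 family at least 2-fold higher, at 21 and 49 counts (log2 ratio 1.20, interval 0.46 to 2.03), and LTR41B the 1 at least 2-fold lower, at 18 and 3 counts (−2.40, interval −4.99 to −0.81). The next highest families were THE1C at 17 and 28 counts, MER51A at 6 and 10, MSTB at 45 and 59, and MER21C at 44 and 55, and the next lowest were LTR16E2 at 9 and 5, PABL_B at 10 and 6, MER57B1 at 23 and 15, and THE1B at 26 and 17, each with an interval that includes 0. Intervals excluded 0 for 3 families above and 9 below in the counts as deposited. After scaling to the table's total, 5 families were higher and 5 lower with an interval that excludes 0, where 2.75 would lie outside by counting error alone.

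**Figure D4:**
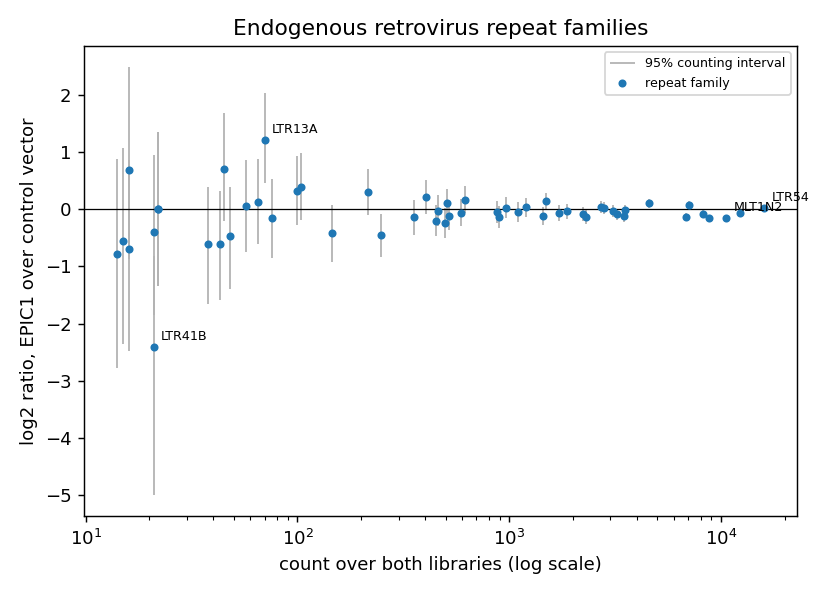
Each point is a repeat family with at least 10 counts, placed by its count over both libraries (log axis) and its log2 ratio, EPIC1 over control, with bars for the 95% counting interval. Families past 1000 counts lie between −0.16 and 0.14, and LTR13A and LTR41B lie farthest from 0.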

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

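Restricting genes by reads or by opposite-strand overlap, the rescaling of the RP11-191L9.4 row to a common sum, and the count of repeat families by interval were chosen after the data were seen. Of the main values, 305 stayed within their bounds under the alternatives, 14 moved and 7, values of 3 lists, kept their sign and left the central range of random lists. Of 286 list medians under an alternative, 35 had the other sign, over 17 lists. Against 2964 genes higher and 3050 lower, a pseudocount of 5 FPKM gave 1364 and 1325, a floor of 5 FPKM gave 1250 and 1280, at least 50 reads at the upper limit gave 274 and 286, and no opposite-strand exon overlap gave 1314 and 1303. Of these, the floor, the read limit and the overlap limit also leave fewer genes to count. The median of mTORC1 and amino acid response genes was 0.76 over the 4 members with at least 50 reads at the upper limit, against 0.27. The nucleic acid sensing median was 1.25 over 5 members with at least 50 reads at the upper limit, against −0.04. It left the central range of random lists, while the mTORC1 list stayed inside. Other lists that left the central range were the estrogen response, hypoxia and glycolysis, and basal epithelial markers. The estrogen response was at 0.55 with a floor of 5 FPKM and 0.34 with at least 50 reads at the upper limit. Hypoxia and glycolysis was at 0.34 with a pseudocount of 5 FPKM and 1.32 without opposite-strand overlap. Basal epithelial markers were at 0.89 with a pseudocount of 5 FPKM, 0.83 with no floor and 1.47 against unmatched lists. The cause was not tested. The mitochondrial median stayed outside under each alternative, though only just against unmatched lists, at percentile 2.36. The RP11-191L9.4 row differed by 8.24 with a pseudocount of 0.1 FPKM and by 2.81 with 5 FPKM, by construction, since it is listed at 0 in the control library. Counting only repeat families whose interval excludes 0 after scaling to the total gave 5 higher and 5 lower, against 19 and 34, and scaling alone gave 27 and 28. For single named genes, 542 values stayed within their interval and 128 moved or had no interval to be judged by. No paired analysis was possible because each group has 1 library and no test was run. Low genes are uncertain, as 19.0% of genes above the floor were listed at 0 in 1 library. Whether depth or the strand counted accounts for these values was not tested.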

Other observations

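All features in this part were chosen after their values were seen. The tests of the mitochondrial rows, including that of reads shared without regard to strand there, that of genes with at least 50 reads, that of the direction of the genes 2-fold apart, and the leaving out of rows from the count of overlaps were chosen only after the result was seen. The others were written before.

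The genes best measured by reads gave differences mostly outside the fixed lists, which hold HIST1H2BH and MT-ND4. Among the 227 genes with 1 transcript and at least 50 reads, the histone genes HIST1H2BG and HIST1H2BH stood at 54.9 and 70.4 FPKM in the control library and at 24.3 and 23.4 in the EPIC1 library, on 49 and 88 reads against 21 and 29. IDI2, an isopentenyl diphosphate isomerase whose row overlaps an opposite-strand exon, was 2.58-fold lower at 70.3 and 27.3 FPKM. Among antisense transcripts, UGDH-AS1 was 2.32-fold higher at 10.3 and 24.0 FPKM, P4HA2-AS1 2.03-fold higher at 59.98 and 122, and ZSWIM8-AS1 2.42-fold lower at 43.1 and 17.8, all rows with such an overlap. AC010168.1, also antisense, was 4.68-fold higher at 412 and 1926 FPKM (128 and 592 reads, interval of the log2 ratio 1.96 to 2.53). AL139288.1 was 4.27-fold lower at 1129 and 264 FPKM, and ATP8A2P2, a pseudogene, 2.18-fold lower at 43.4 and 19.9, both rows with an opposite-strand exon overlap. NEAT1, the noncoding RNA that builds paraspeckles, was within the 2-fold bound, 1.97-fold higher at 14.2 and 27.98 FPKM. No read number is given for it here, so it is not shown to be among the best measured.

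Rows that lie antisense to abundant genes stand high in the gene table, and a candidate explanation is that reads were counted on the strand opposite to the transcript, since the kit named in the labels marks strand. The share of rows with an opposite-strand exon overlap was 1.39 times as high among the 100 highest rows as among the others (interval 1.16 to 1.61). This was under the 1.5 set in advance as speaking against this explanation, but not beyond its interval. The ratio was 1.47 with small and short rows left out, and 1.62 with mitochondrial rows left out too. It cannot decide the question, because 44.5% of the other rows overlap too and the highest rows include mitochondrial rows without an overlap. The -AS1 row was above its protein-coding partner in 54.4% of 377 pairs in the control library (exact 95% interval 49.2 to 59.5) and 56.5% in the EPIC1 library (51.3 to 61.6). These shares are past the 50% predicted, but not beyond its interval in both, a bar set after the values were seen. The bar set in advance as speaking against opposite-strand counting was fewer than 25%, and both intervals lie above it. All 8 pairs found for ribosomal protein and housekeeping genes held a ribosomal protein gene, whose row was the lower in 25%. This fits the prediction for reads shared without regard to strand, but counting on the transcript's own strand would give it too. The pairs therefore cannot tell them apart. The mitochondrial rows argue against reads shared without regard to strand, with MT-ND6 15.2 times MT-CO1 in the control library. Opposite-strand counting stays open for the table as a whole, rows without an overlap included. The ribosomal protein pairs do not decide it for those genes, because an exon overlap of any length made a pair. No biological explanation was tested.

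Of the genes at least 2-fold apart, centring left 99.98%, but the median difference it removed was −0.0013 on the log2 scale, so it decides nothing. A difference in scaling is argued against as the cause by direction, since 49.3% of these genes were higher. A library scaled too low or too high would put them mostly on 1 side. FPKM are already scaled to depth, so direction does not bear on depth itself. Counting noise could account for most of the low genes, as 348 single-transcript genes were at least 2-fold apart, above the highest of 100 splits, 326, but by less than 1.5 times. For genes with at least 50 reads it is argued against, with 11 observed and at most 3 in any split. An effect of EPIC1 and a difference between any 2 cultures or library preparations stay open, since the design, with 1 library per group, does not separate them.

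Of the mitochondrial rows, 12 were lower in the EPIC1 library and MT-ND6 was higher. Counting noise is argued against, as 0 of the 12 counting intervals included 0, and so is the scaling of the libraries, since the median of all genes lay 0.70 above the median of the 12 rows on the log2 scale. Opposite-strand counting is in line with MT-ND6, the light-strand mRNA, standing 3.19 times above the highest other row in the control library, because its row would then hold reads of the heavy-strand transcripts. Under that reading the 12 rows may hold light-strand RNA, and the direction of their mRNAs would not be known. The MT-ND6 row covers only its own stretch and would not give it for the others. A change of mitochondrial transcription with EPIC1 and a difference between the cultures stay open and were not tested.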
